A study of Mus musculus with 2 samples.

How the data were processed

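The authors deposited raw UMI counts per gene and barcode for each library, with 30905 genes, and all comparisons here start from those counts. The submitters' processing notes give Cell Ranger 3.1.0 and the mm10 assembly for both libraries, and the matrix headers name the same version. Per the labels the nuclei came from frozen tissue through a sucrose gradient, and the libraries were made with 10x Genomics 3' v3.1 chemistry and sequenced on a NovaSeq 6000. Whether intronic reads were counted, and whether free RNA or doublets were removed upstream, is not given in the sources used here. Of the gene identifiers, 30843 were found in GENCODE M21, and 65 symbols shared by several identifiers were kept apart by identifier. The barcodes of the 2 libraries overlapped at 14 sequences and were treated as different nuclei.

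Nuclei were kept with at least 500 detected genes and under 10% mitochondrial UMIs. Scrublet, as built into scanpy, called doublets per library with an expected rate of 6%, and its automatic threshold was used. It called 246 barcodes in each library, 3.33% of mTBI and 3.14% of Sham barcodes. The mitochondrial limit removed 71 mTBI and 100 Sham barcodes, the gene limit 0 and 2, and a cluster that carried oligodendrocyte and granule neuron markers together another 12 and 6. The kept mTBI nuclei held 57528330 UMIs with a median of 6761.5, and the kept Sham nuclei 59557318 UMIs with a median of 6514. Both libraries were joined, scaled to 10000 UMIs per nucleus, log-transformed and reduced to 2000 variable genes and 40 principal components with values clipped at 10. A graph of 20 neighbours was clustered with the Leiden algorithm at a resolution of 1 and seed 0, without batch integration, giving 35 clusters. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, scanpy 1.11.5, scikit-learn 1.9.0, python-igraph 0.11.9 and matplotlib 3.10.9 were used.

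The filters, markers of 25 cell classes, 40 gene lists, comparisons, rule for named genes and alternative settings were chosen before the data were examined. The scoring that turned markers into cluster names was set afterwards. A cluster took the class whose markers had the highest mean log2 fold, if at least 3 of them, and at least 50% of those detected (20 UMIs), were 2-fold above the other clusters. It also stayed unnamed where a class of another lineage had at least 4 markers at 2-fold and a mean of at least 30% of the best, or where its median depth was under 1/3 of the library median in each library and under 3 markers were among its top 10 genes. A cluster with both microglia and cycling markers was joined to the microglia-like class, also after the data were seen. The labels assign no cell types, so all names describe marker patterns. Classes with at least 50 kept nuclei in each library were compared, which gave 14. Smaller classes were not compared: Cajal-Retzius-like (38 mTBI and 48 Sham nuclei), mossy-like (32 and 37), pericyte-like (35 and 29) and perivascular macrophage-like (9 and 10).

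UMIs were summed per library and class and divided by the class total. The log2 ratio of mTBI over Sham was given for genes with at least 50 UMIs in the class, with an exact conditional 95% interval for the ratio of 2 Poisson rates. Shares of nuclei carry Clopper-Pearson intervals. A gene at 0 in a library was set to a floor of 3 counts in that library. A list needed at least 5 measured members in a class. Its median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 40 bins, and its interval came from 1000 resamples of the counts. In all 364 pairs of list and class were computed, and those described were picked after their values were seen. For shares of nuclei with a UMI, nuclei were thinned without replacement to 1 number of UMIs per class, the 10th percentile over the nuclei of the class, and shallower nuclei were left out.

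Genes are named by 3 rules. The first takes, within each class, the 5 genes with the highest and the 5 with the lowest interval bound nearest 0, or 10 and 10 in the 2 largest classes. Mitochondrial, ribosomal protein, haemoglobin and sex-linked genes, and gene models named Gm plus a number or ending in Rik, were not ranked. The second takes up to 4 members of a list with the largest bound, and exceptions to its direction. The third takes the 5 genes higher and the 5 lower, by over 1.5-fold, in the most classes. The first rule gave 160 pairs of gene and class, and the text gives a selection of them that was made after their values were seen. Mbp and Cldn5, and the 2 highest-ranked genes outside the Gm and Rik models printed with each unnamed cluster, were chosen after their values were seen.

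The ratio step was tested on simulated data of the size of the granule-like and microglia-like classes, in which 12673 and 5050 genes were assessed. The simulated counts were independent Poisson draws from 1 profile pooled over both libraries. They held no clumping of UMIs in single nuclei and no variation between animals. The rates below therefore apply to counting error alone, and do not carry over to genes with many UMIs in 1 nucleus. The interval excluded 1 for 98.4% and 89.2% of genes set to a 2-fold difference, for 87.7% and 61.9% at 1.5-fold, and for 4.69% and 3.84% of genes with no difference. Of 200 lists with no difference, 10 and 11 fell outside the middle 95% of random lists, and of 200 lists moved by 0.5 in log2 all 200 did so in both classes.

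The alternative settings were minimum genes of 200 and 1000, a mitochondrial limit of 2% or none, doublets kept, cluster resolutions of 0.5 and 2, each library clustered alone, minimum UMIs of 20 and 200, size factors, totals without mitochondrial, ribosomal protein and Malat1 counts, means over nuclei, thinned counts, and shares among neurons or non-neuronal nuclei alone. Added after the data were seen were microglia-like nuclei without the cycling cluster, genes without the nucleus holding most of their UMIs, and the largest cluster of a class alone. Raw reads were not used here.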

Results

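Single-nucleus RNA sequencing measured polyadenylated transcripts in nuclei from the mouse hippocampus 48 hours after a mild controlled cortical impact, in which a piston strikes the exposed brain (mTBI), or after sham surgery (Sham). The labels give hippocampi of 3 mice per group, 8 to 10 weeks old, and 1 library per group. How the tissue of the 3 mice was combined is not stated. With 1 library per group no difference was tested, and no value carries an error between animals. Ranges in parentheses are exact 95% intervals (Poisson or Clopper-Pearson), or, beside list medians, 95% ranges from resampled counts, and all cover counting error only. The mTBI library held 7395 barcodes with 61065687 unique molecular identifiers (UMIs), a median of 6833 per barcode. The Sham library held 7834 barcodes with 62908583 UMIs, a median of 6567.5. After filtering, 7068 mTBI and 7486 Sham nuclei remained. The question the comparison addresses is which hippocampal cell classes and genes differ between injured and sham-operated animals at 48 hours.

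Neurons, with unnamed clusters that scored closest to a neuronal class included, made up the same share of both libraries within counting error. Endothelial-like nuclei were more frequent, and granule-like and oligodendrocyte-like nuclei less frequent, in the mTBI library. Neuronal classes and these unnamed clusters held 65.7% of mTBI nuclei (64.6–66.8, 4644 nuclei) and 65.3% of Sham nuclei (64.2–66.4, 4890 nuclei). The unnamed clusters counted here were led by Ano1 and Cpa6, Npsr1 and Pdzrn3, Gpc3 and Col23a1, Col6a1 and L3mbtl4, and Cpa6 and Il1rapl2. The share of the named neuronal classes alone is not given here. Dentate granule-like neurons, the input neurons of the hippocampus, were 19.5% of mTBI nuclei (18.6–20.5) and 23.2% of Sham nuclei (22.2–24.1), a ratio of 0.843 (0.785–0.905). Oligodendrocyte-like nuclei, from the myelinating cells, were 11.3% and 14.1%, a ratio of 0.804 (0.732–0.882). Endothelial-like nuclei, from the vessel lining, were 2.07% of mTBI nuclei (1.75–2.42; 146 nuclei) and 0.935% of Sham nuclei (0.730–1.18; 70 nuclei), a ratio of 2.21 (1.65–2.98). When each library was clustered alone that ratio was 1.16. Vascular leptomeningeal fibroblast-like nuclei had a ratio of 1.43 (1.11–1.86). CA3-like pyramidal neurons had a ratio of 1.17 (1.02–1.35), which became 2.32 with each library clustered alone. Subicular or deep-layer-like projection neurons had a ratio of 1.31 (1.15–1.49), which turned to 0.80 under the same alternative. Microglia-like nuclei, from the resident immune cells, were 3.62% and 3.49%, a ratio of 1.04. Astrocyte-like nuclei were 5.90% and 6.93%, a ratio of 0.851 (0.746–0.970). Rules set after the data were seen left 7 clusters without a name, and these held 1.53% and 2.18% (Ano1, Cpa6), 3.81% and 1.79% (Npsr1, Pdzrn3), 2.24% and 0.761% (Mgp, Gfap), 2.35% and 2.15% (Gpc3, Col23a1), 1.68% and 1.75% (Col6a1, L3mbtl4), 0.156% and 0.107% (Myh11, Acta2), and 2.04% and 1.24% (Cpa6, Il1rapl2) of mTBI and Sham nuclei. The cluster led by Mgp and Gfap was shallow, with median depths of 1419 and 1118 UMIs.

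**Figure D1:**
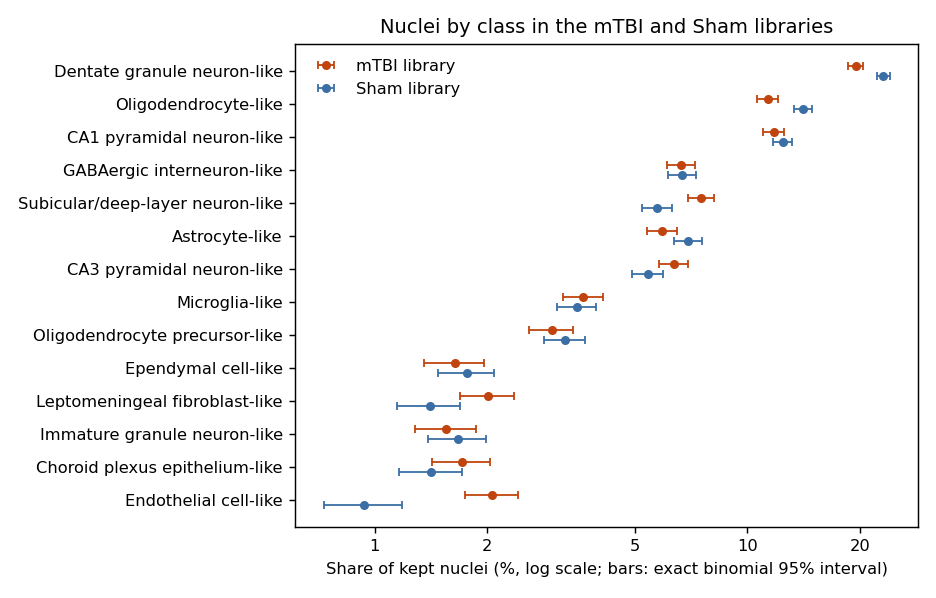
Share of kept nuclei in percent (log axis) for the 14 compared classes in the mTBI and Sham libraries; dots are shares and bars are exact 95% binomial intervals. Endothelial-like nuclei were 2.07% of the mTBI and 0.935% of the Sham library, and granule-like neurons 19.5% and 23.2%.

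In astrocyte-like nuclei, genes of the reactive state were higher in the mTBI library. Gfap, the intermediate filament that marks reactive astrocytes, had 447 UMIs in 417 mTBI nuclei and 137 in 519 Sham nuclei, 3.83-fold higher in the mTBI library (3.16–4.67). Cd44, a receptor for the matrix sugar hyaluronan, was 3.67-fold higher (2.29–6.08), Osmr, a cytokine receptor subunit, 4.38-fold (2.21–9.44), and Vim, another intermediate filament, 3.15-fold (1.90–5.40). All 5 measured pan-reactive astrocyte genes were higher, with a median log2 ratio of 1.88 (1.39–2.13). The 95% range of random lists matched on expression was -0.29 to 0.36. The median of this list lay above the middle 95% of random lists in all 5 classes measured, down to 0.38 in endothelial-like nuclei. Vim was at 0.141 UMIs per nucleus in mTBI astrocyte-like nuclei, against a median of 0.0742 in the other classes. Stat3, a transcription factor of that list, was at 0.27. A2m, a protease inhibitor, was 6.39-fold higher (3.11–14.8), although 36.7% of its mTBI UMIs lay in 1 nucleus, and its log2 ratio was 2.38 without that nucleus and 4.36 after thinning. Gfap UMIs also lay in other classes, at a median over those classes of 0.213 per nucleus in the mTBI and 0.0372 in the Sham library, against 1.07 and 0.264 in astrocyte-like nuclei. With those levels subtracted the Gfap fold was 3.79. A Gfap UMI was found in 43.2% of mTBI (38.4–48.1) and 18.5% of Sham astrocyte-like nuclei (15.2–22.1), at median depths of 2839 and 2732 UMIs. After thinning to 1804 UMIs these shares were 32.7% and 13.2%. In microglia-like nuclei, with median depths of 2208.5 and 1831 UMIs, the Gfap shares were 18% and 3.45%, or 16.7% and 3.68% after thinning. Thinned astrocyte-like shares for Osmr were 4.97% (3.02–7.66) and 1.08% (0.353–2.51). The intervals overlapped for Cd44, at 6.02% (3.85–8.90) and 2.39% (1.20–4.23), and for A2m, at 2.09% (0.908–4.08) and 0.651% (0.134–1.89). They also overlapped for Vim, at 5.50% (3.43–8.28) and 2.82% (1.51–4.77), and mTBI microglia-like nuclei had Vim at 5%.

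Genes of cholesterol synthesis and transport were also higher in mTBI astrocyte-like nuclei, whereas single genes such as Mertk and Htra1 were lower. Among 14 measured genes of cholesterol synthesis and transport, 13 were higher, with a median log2 ratio of 0.41 (0.21–0.51), at percentile 100 of random lists. Fdft1, which commits precursors to sterol synthesis, was at 0.73, Insig1, a sterol sensor, at 0.74, and Apoe, the main lipid carrier of the brain, at 0.33. Abca1, a lipid exporter, was the exception at -0.19. Mertk, a receptor for engulfing dying cells and synapses, had 924 mTBI and 1783 Sham UMIs and was 1.64-fold higher in the Sham library (1.52–1.78). Htra1, a secreted protease, was 1.77-fold higher in the Sham library (1.56–2.00), Folh1, a glutamate carboxypeptidase, 2.11-fold (1.63–2.74), and Unc13c 2.09-fold (1.57–2.80). In the list of extracellular matrix and perineuronal net genes 4 of 11 members were higher, and the median was -0.33 at percentile 0.06. Its proteoglycans Vcan (-0.81) and Bcan (-0.35) and the link protein Hapln1 (-0.43) were lower, and Tnr (0.59) higher; the median was 0.05 among members with at least 200 UMIs. Of the astrocyte homeostasis genes 3 of 12 were higher, with a median of -0.07, but the water channel Aqp4 was 1.75-fold higher in the mTBI library (1.51–2.03).

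Cell-cycle transcripts were present in a subset of microglia-like nuclei of the mTBI library and nearly absent from those of the Sham library. Top2a, the DNA topoisomerase of dividing cells, had 73 UMIs in 29 mTBI microglia-like nuclei and 0 in the Sham library, at least 18-fold higher in the mTBI library against a floor of 3 counts in the Sham library, with an exact lower 95% bound of 14.3-fold. Kif15, a mitotic motor, was 15.3-fold higher (4.99–76.2), Diaph3, a regulator of the actin skeleton, 12.1-fold (4.99–38.4), and the non-coding RNA Lockd 49.6-fold (8.60–1987), from 67 UMIs and 1. With doublets kept, Diaph3 was at a log2 ratio of 2.53. After thinning, the log2 ratios were 3.33 for Top2a against the floor, 3.28 for Kif15, 4.86 for Diaph3 and 4.76 for Lockd. UMIs of at least 2 of 6 cycling markers were found in 31 of 256 mTBI nuclei, 12.1% (8.38–16.7), and in 0 of 261 Sham nuclei, which allows a share of up to 1.15% by the floor of 3 counts and 1.40% by the exact interval. Median depths were 2208.5 and 1831 UMIs. After thinning to 1299 UMIs the shares were 9.75% of 236 mTBI nuclei (6.28–14.3) and 0 of 229 Sham nuclei. In CA1-like neurons, with median depths of 10949.5 and 11194 UMIs, the shares were 0.12% and 0.215%, and 0 in both after thinning. Of the microglia-like nuclei 27, all from the mTBI library, formed a cluster of their own, and without it Kif15 was at a log2 ratio of 0.50 and Diaph3 at 1.25.

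Disease-associated microglia genes were slightly higher in mTBI microglia-like nuclei, while homeostatic genes leaned lower without leaving the middle 95% of random lists. Of 12 measured homeostatic microglia genes 1 was higher, and the median log2 ratio was -0.24 (-0.32 to -0.14), at percentile 2.73 and -0.09 as a mean over nuclei. Sall1, a transcription factor of microglia identity, was at -0.58, Gpr34 at -0.43, Selplg at -0.35 and P2ry12, a receptor for ADP, at -0.30; Sparc was the exception at 0.09. Of 8 disease-associated microglia genes 7 were higher, with a median of 0.31 (0.09–0.46) at percentile 99.3. Fth1, an iron-storage subunit, was at 0.34, and B2m was the exception at -0.15. Apoe was at 0.35, which turned to -0.41 at a cluster resolution of 0.5 and with each library clustered alone. Apoe stood at 1.14 and 0.651 UMIs per nucleus in the mTBI and Sham libraries. That is near the 1.02 and 0.728 in granule-like neurons, and below the 4.63 and 3.48 in astrocyte-like nuclei. The median of this list also lay above the middle 95% of random lists in 10 of 12 classes, at 0.56 in granule-like and 0.60 in CA1-like neurons. Ccnd3, a cyclin, was 1.96-fold higher in the Sham library (1.69–2.29), and Cds1 2.08-fold (1.47–2.96).

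Genes that respond to glucocorticoid hormones were lower in oligodendrocyte-like and astrocyte-like nuclei of the mTBI library, with the lowest median in the former. Among 10 measured members 9 were lower there, with a median log2 ratio of -0.98 (-1.34 to -0.83), at percentile 0 of random lists whose 95% range was -0.18 to 0.20. Fkbp5, a co-chaperone of the glucocorticoid receptor, had 80 UMIs in 802 mTBI nuclei and 309 in 1057 Sham nuclei, 3.13-fold higher in the Sham library (2.44–4.05). Zbtb16, a transcription factor, was 2.54-fold higher in the Sham library (2.17–2.98), Sgk1, a kinase induced by the hormone, 2.62-fold (2.16–3.21), and Arrdc2 2.91-fold (2.01–4.31). Plin4, a lipid droplet protein, had 6 and 60 UMIs and was 8.10-fold higher in the Sham library (3.51–22.9); its log2 ratio was -3.02, and -2.28 at a cluster resolution of 2, which left 1068 nuclei with oligodendrocyte markers unnamed. Tsc22d3 was at -0.56, and Ddit4 was the exception at 0.09. Fkbp5 stood at 0.0998 and 0.292 UMIs per nucleus in the mTBI and Sham libraries, below the medians of 0.461 and 0.437 in the other classes. Zbtb16 and Sgk1 also lay below the medians of the other classes in both libraries, whereas Plin4 in the Sham library was at 9.82 times that median. These levels were not adjusted for depth. Median depths were 2475 and 2230 UMIs in oligodendrocyte-like nuclei against, for example, 7312 and 7350.5 in granule-like neurons. In astrocyte-like nuclei 0 of 6 members were higher, at a median of -0.53 (-0.80 to -0.29; percentile 0.02). Fkbp5 in microglia-like nuclei was 2.51-fold higher in the Sham library (1.99–3.18) and Tsc22d3 2.46-fold (1.43–4.34), but too few members were measured there for a list value. Endothelial-like nuclei had a median of -0.75 at percentile 0.025, which became 0.02 after thinning. Neuronal medians were near 0, at -0.06 in granule-like and -0.08 in CA1-like neurons and 0.06 in GABAergic-like interneurons. Subicular or deep-layer-like neurons were at -0.20 (percentile 0.44).

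Other oligodendrocyte-like transcripts were lower in the mTBI library while myelin genes were level. Hif3a, a hypoxia-inducible factor subunit, was 4.98-fold higher in the Sham library (2.76–9.76), Ptgds, which makes prostaglandin D, 2.09-fold (1.81–2.42), Rcan2, a calcineurin inhibitor, 2.04-fold (1.79–2.34), and Adipor2, an adiponectin receptor, 1.74-fold (1.58–1.92). Pdlim2 was 2.68-fold (1.70–4.32) and Adamts2, a collagen-processing protease, 1.82-fold (1.49–2.23) higher in the mTBI library. Of 14 myelin genes 11 were higher, with a median log2 ratio of 0.03. Mobp was at -0.43, Opalin at 0.34, Mag at 0.21 and Mbp at 0.03. Higher values of Gfap and Vim in this class did not exceed the median UMIs per nucleus of the other classes.

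**Figure D2:**
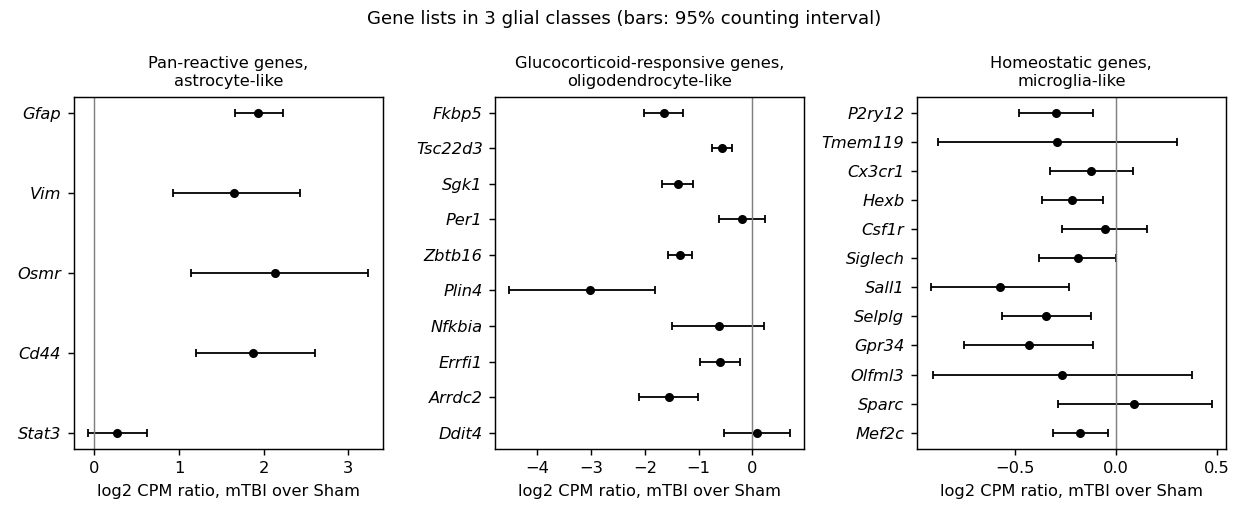
Log2 ratios of mTBI over Sham for the measured members of 3 gene lists: pan-reactive genes in astrocyte-like, glucocorticoid-responsive genes in oligodendrocyte-like and homeostatic genes in microglia-like nuclei; dots are ratios and bars are 95% counting intervals. The list medians were 1.88, -0.98 and -0.24.

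Key genes lie at these positions of the mouse assembly mm10 (GRCm38, GENCODE M21): Gfap (ENSMUSG00000020932) on chromosome 11 from 102887336 to 102900912, Cd44 (ENSMUSG00000005087) on chromosome 2 from 102811141 to 102901665, Mertk (ENSMUSG00000014361) on chromosome 2 from 128698956 to 128802894, and Top2a (ENSMUSG00000020914) on chromosome 11 from 98992943 to 99024189. Fkbp5 (ENSMUSG00000024222) lies on chromosome 17 from 28399094 to 28517527, Zbtb16 (ENSMUSG00000066687) on chromosome 9 from 48654297 to 48836222, Arc (ENSMUSG00000022602) on chromosome 15 from 74669083 to 74672570, Bdnf (ENSMUSG00000048482) on chromosome 2 from 109674700 to 109727007, and Tox (ENSMUSG00000041272) on chromosome 4 from 6686353 to 6991557. All of them are annotated as protein-coding.

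Immediate early genes, which neurons switch on with electrical activity, went in different directions in the neuronal classes. In dentate granule-like neurons 11 of 15 measured members were higher in the mTBI library, with a median log2 ratio of 0.26 (0.06–0.38), at percentile 99.4 and 0.16 to 0.29 over the alternatives. Jun, a transcription factor of stress and activity, was at 0.57, Btg2 at 0.50, and Bdnf, a growth factor for synapses, at 0.44 (1478 and 1298 UMIs). Arc, a regulator of synaptic receptors, was among the exceptions at -1.24 (21 and 59 UMIs), and -1.87 after thinning. In CA1-like neurons 6 of 16 members were higher, and the median was -0.22 (-0.35 to -0.04), at percentile 0 and -0.30 to -0.11 over the alternatives. Nr4a2, an orphan nuclear receptor, was at -0.70 there, Nr4a3 at -0.56, Arc at -0.56, and Homer1, a postsynaptic scaffold, at -0.43 (2472 and 3767 UMIs). In CA3-like neurons 4 of 14 were higher, with a median of -0.15 (percentile 0.67), which became 0.02 with each library clustered alone. Arc was at -1.03, Bdnf at -0.50 and Homer1 at -0.26 in that class. Nptx2, a pentraxin of synapses, was among the exceptions there at 1.24 (48 and 20 UMIs). It was at 3.28 at a cluster resolution of 2 and 4.88 with each library clustered alone. In subicular or deep-layer-like neurons 3 of 14 were higher, with a median of -0.22 at percentile 0, which became 0.03 and 0.07 at cluster resolutions of 0.5 and 2. Arc was at -1.19, Nr4a3 at -1.03 and Jun at 0.88 in those neurons. The other 5 of the 9 classes measured had medians within the middle 95% of random lists.

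**Figure D3:**
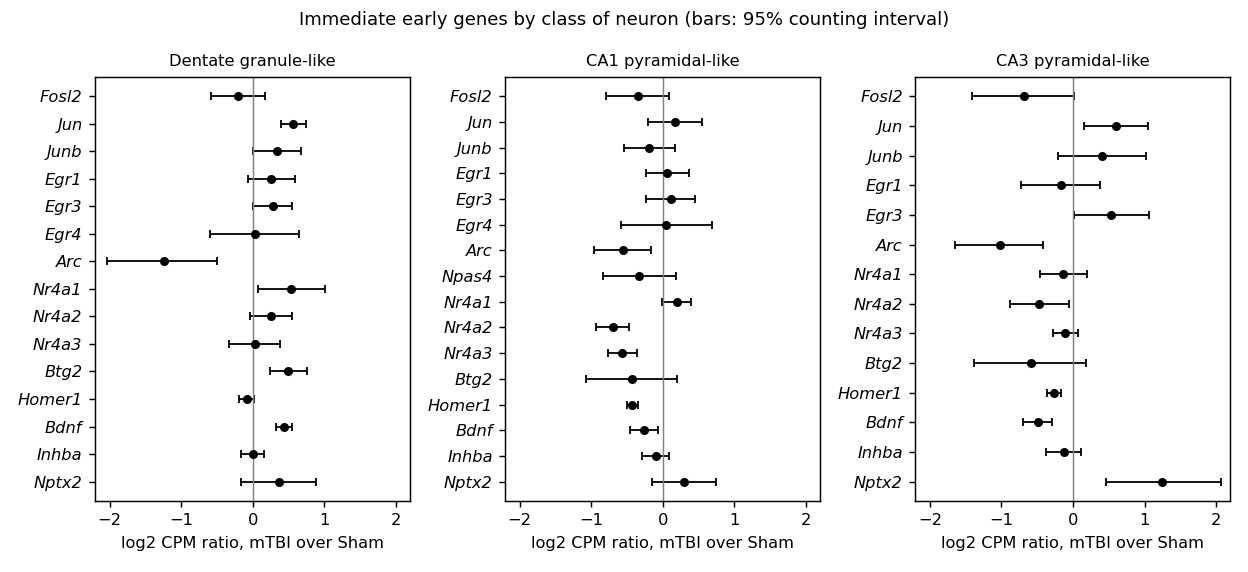
Log2 ratios of mTBI over Sham for immediate early genes in granule-like, CA1-like and CA3-like neurons; dots are ratios and bars are 95% counting intervals. The medians were 0.26, -0.22 and -0.15, and Arc was lower in the mTBI library in all 3 classes.

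Dentate granule-like neurons also differed in single genes. Tox, a chromatin-binding factor best known from T cells, had 882 UMIs in 302 mTBI nuclei and 199 in 150 Sham nuclei, 5.27-fold higher in the mTBI library (4.51–6.17). Its level was 0.639 and 0.115 UMIs per nucleus, against medians of 0.253 and 0.439 in the other classes. Mei1 was 2.87-fold higher in the mTBI library (1.93–4.36). Chst9, a sulfotransferase for sugar chains, had 2636 and 5266 UMIs and was 1.68-fold higher in the Sham library (1.60–1.76). Hectd2, a ubiquitin ligase, was 1.60-fold (1.51–1.71), Tspan18, a membrane scaffold, 1.67-fold (1.54–1.81), Rhbdl3 1.91-fold (1.64–2.21), and Lgr6, a Wnt co-receptor, 2.44-fold (1.67–3.62) higher in the Sham library. Gfap was 6.16-fold higher in the mTBI library in these neurons, at 0.241 UMIs per nucleus, close to the median of 0.213 in the other classes.

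Pyramidal neurons differed in further single genes. Tiparp, an enzyme induced by the aryl hydrocarbon receptor, was 2.09-fold higher in the Sham library in CA1-like neurons (1.68–2.61), at 0.142 and 0.3 UMIs per nucleus against medians of 0.171 and 0.229 in the other classes. Prlr, the prolactin receptor, was 2.10-fold (1.66–2.68), Pcsk1, a prohormone convertase, 2.09-fold (1.64–2.68), and Adamts2 1.97-fold (1.62–2.40) higher in the Sham library in CA1-like neurons. In CA3-like neurons Nefl, the light neurofilament chain, had 424 and 187 UMIs and was 2.23-fold higher in the mTBI library (1.87–2.66), and Rgs4, a brake on G-protein signalling, 3.04-fold (2.02–4.68). Rgs4 was at 0.221 and 0.0792 UMIs per nucleus in the mTBI and Sham libraries, against medians of 0.145 and 0.105 in the other classes. Of 10 axonal injury and regeneration genes 9 were higher in CA3-like neurons, with a median log2 ratio of 0.33 (0.17–0.46) at percentile 99.8, including Nefm at 0.53, Gap43, a growth cone protein, at 0.38, and Basp1 at 0.31. The median of this list was above the middle 95% of random lists in 10 of 13 classes. Sorcs3, a sorting receptor, was 1.91-fold higher in the Sham library (1.76–2.07) in CA3-like neurons; its log2 ratio was -0.93, and -0.18 with each library clustered alone. Cyp2j6, a fatty acid oxidase, was 2.60-fold higher in the Sham library in subicular or deep-layer-like neurons (1.57–4.43).

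Neuropeptide transcripts were higher in GABAergic-like interneurons of the mTBI library. All 9 measured members were higher, with a median log2 ratio of 0.63 (0.41–0.74) at percentile 100, and 0.42 to 0.76 over the alternatives. Npy, an inhibitory peptide, was 1.95-fold higher (1.45–2.64), Sst, the marker peptide of a major interneuron group, 1.76-fold (1.54–2.02), and the granule proteins Scg2 and Chgb were 1.74-fold (1.38–2.2) and 1.62-fold (1.37–1.91) higher. Neuropeptides were also higher in granule-like (10 of 11, median 0.34) and CA1-like neurons (7 of 8, median 0.35), and above the middle 95% of random lists in 7 of 11 classes. Hs3st4, a heparan sulfate sulfotransferase, was 2.89-fold higher in mTBI interneurons (2.52–3.33). Klhl14 was 2.66-fold (1.74–4.17) and Piezo2, a mechanically gated channel, 2.63-fold (1.59–4.48) higher in the Sham library.

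Some transcripts were higher in nearly every class of the mTBI library. Gfap was higher in 10 of 10 measured classes, with a median log2 ratio of 2.33, the mitochondrial tRNA synthetase gene Lars2 in 11 of 14 (0.75), Slc25a4, the mitochondrial ADP and ATP carrier, in 10 of 14 (0.64), the tubulin gene Tuba1b in 9 of 14 (0.82) and the metallothionein gene Mt1 in 9 of 14 (0.74), counting ratios over 1.5 with intervals above 1. Prom1 was lower in 4 of 5 classes, Arc in 3 of 4, Noxred1 in 3 of 4, Pcsk1 in 3 of 5 and Smo, the Hedgehog signal transducer, in 3 of 7. Nuclear-encoded oxidative phosphorylation genes had a median above 0 in 14 of 14 classes, from 0.17 in immature granule-like to 0.56 in ependymal-like nuclei. Cytosolic ribosomal protein genes had medians above 0 in 10 of 10 classes, from 0.22 to 0.74. The mTBI excess in UMIs per nucleus was similar in shallow and deep classes for several of these. Shallow classes had median depths under 4000 UMIs and were all non-neuronal. Deep classes had median depths over 6000 UMIs and were all neuronal. Immature granule-like and choroid plexus-like nuclei were in neither set. The ratio of deep over shallow was 1.16 for Tuba1b, 1.16 for Mt1, 1.20 for oxidative phosphorylation and 1.35 for ribosomal protein genes. For Gfap it was 1.12, with the astrocyte-like and ependymal-like classes (excess 0.808 and 0.264) left out of the shallow classes. The mean of the class median depths was 3.71-fold higher in deep than in shallow classes, and 3.90-fold higher for the classes used for Gfap. The ratio of excess was 0.860 for Ttr and 0.401 for Apoe, but 2.32 for Malat1, 3.30 for Vim and 5.93 for Slc17a7. The Vim value includes the endothelial-like class, which held 1.10 and 1.30 Vim UMIs per nucleus in the mTBI and Sham libraries.

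**Figure D4:**
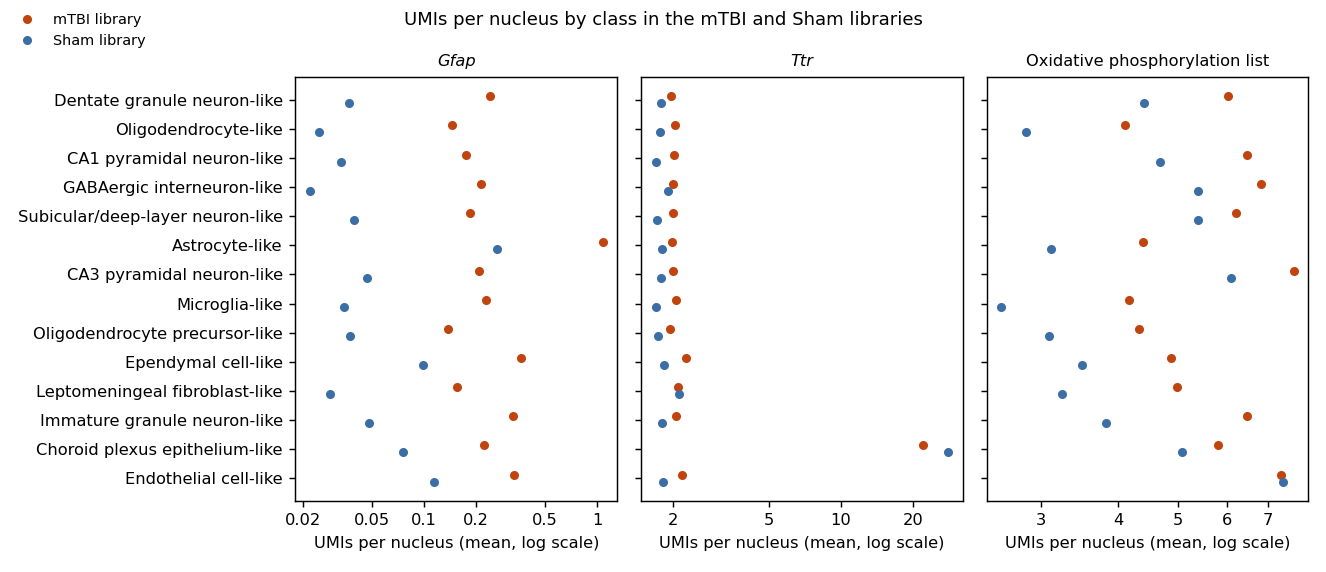
Mean UMIs per nucleus (log axis) of Gfap, Ttr and the oxidative phosphorylation list in the 14 classes of the mTBI and Sham libraries; each dot is 1 class in 1 library. Gfap in classes other than astrocyte-like was at a median near 0.213 in the mTBI and 0.0372 in the Sham library.

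Mitochondrially encoded transcripts were higher in most classes of the mTBI library and lower in a few. Their median was above 0 in 10 of 14 classes, above the middle 95% of random lists in 9 and below it in 2. In CA3-like neurons 11 of 11 were higher in the mTBI library, with a median log2 ratio of 0.94 (0.88–0.97), and in CA1-like neurons 11 of 11, with a median of 0.32. In granule-like neurons 0 of 11 were higher, with a median of -0.42 (-0.46 to -0.40), and in choroid plexus-like nuclei 0 of 10, with a median of -0.82 (-0.89 to -0.70). With nuclei limited to a mitochondrial share under 2% these medians were 0.76 in CA3-like, -0.27 in granule-like and -0.30 in choroid plexus-like nuclei. Mitochondrial UMIs in nuclei can come from cytoplasm carried along or from free RNA, and these sources were not told apart. The median share per barcode was 0.413% in the mTBI and 0.368% in the Sham library.

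Adult neurogenesis genes leaned lower in immature granule-like nuclei of the mTBI library, without leaving the middle 95% of random lists. All 5 measured members were lower, with a median log2 ratio of -0.30 (-0.52 to -0.06) at percentile 2.98, and -0.43 to -0.11 over the alternatives. Dcx, a microtubule protein of migrating neuroblasts, was at -0.61 (143 and 158 UMIs), and Sox11 and Igfbpl1 were at -0.30. Cdh13, a cell adhesion protein, was 2.84-fold higher in the mTBI library (2.2–3.70), and its log2 ratio was 1.22 to 2.10 over the alternatives. Nell1 was 2.52-fold (1.99–3.20) and Fgf13, a sodium channel partner, 1.86-fold (1.62–2.13) higher in the Sham library. This class held 110 mTBI and 125 Sham nuclei with median depths of 5187 and 3298 UMIs.

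Endothelial-like nuclei showed no common direction of blood-brain barrier genes. Of 14 measured members 4 were higher in the mTBI library, with a median log2 ratio of -0.08 at percentile 38.9. Slc16a1, a lactate transporter, was 1.77-fold higher in the mTBI library (1.30–2.45), whereas the drug exporters Abcg2 and Abcb1a were 1.51-fold (1.28–1.78) and 1.34-fold (1.18–1.52) higher in the Sham library. Mfsd2a, the lipid transporter that keeps the barrier tight, was 1.83-fold higher in the Sham library (1.22–2.75); its log2 ratio of -0.88 became -0.04 under a mitochondrial limit of 2% and -1.68 after thinning. Cldn5, the main tight junction claudin, was at a log2 ratio of 0.04. Genes typical of other classes also differed in endothelial-like nuclei. Ranbp3l, a leading gene of the fibroblast-like class, was 6.51-fold higher in the mTBI library (2.85–18.3), with 39.7% of its UMIs there in 1 nucleus. Slc7a11, another leading gene of that class, stood at 1.84 and 0.386 UMIs per nucleus in endothelial-like nuclei of the mTBI and Sham libraries. The endothelial-like cluster also scored for pericyte or smooth muscle markers, at a mean log2 fold of 4.31 against 7.16 for endothelial markers. Erbb4, an interneuron marker, had a log2 ratio of -2.83, with 69.9% of its Sham UMIs in 1 nucleus, and -1.29 without that nucleus.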

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

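The tests of depth and free RNA for cycling markers, of few nuclei and time of day for glucocorticoid-responsive genes, and of free RNA, and of gene length in the remaining pairs, for the widespread transcripts were chosen only after the result was seen.

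Immediate early genes had opposite directions in neuronal classes, with a median log2 ratio of 0.26 in granule-like, -0.22 in CA1-like, -0.22 in subicular or deep-layer-like and -0.15 in CA3-like neurons, and the difference between classes was not tested. Mitochondrially encoded transcripts had a median of -0.42 in granule-like and 0.94 in CA3-like neurons, and this difference was not tested either. The unnamed cluster led by Mgp and Gfap held 2.24% of mTBI and 0.761% of Sham nuclei, a ratio of 2.94, at median depths of 1419 and 1118 UMIs. Its next leading genes were Rplp1, Cst3, Rpl19 and Ttr, and how far free RNA shaped this cluster was not tested. The unnamed cluster led by Npsr1 and Pdzrn3 held 3.81% and 1.79%. The unnamed cluster led by Cpa6 and Il1rapl2 held 2.04% and 1.24%. These 3 clusters stand outside the compared classes, and their shares were higher in the mTBI library by more than counting error.

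Cycling-marker UMIs were found in microglia-like nuclei of the mTBI library. Depth is argued against, since after thinning to an equal number of UMIs 9.75% of mTBI nuclei (6.28–14.3) still had at least 2 of the 6 markers, above the upper bound of 1.60% in the Sham library. Free RNA is argued against, since free RNA adds a like number of UMIs to every droplet and at most 0.669% of unthinned CA1-like mTBI nuclei had 2 markers (upper bound), against at least 8.38% of unthinned microglia-like nuclei, and doublets with another class are argued against, since the cycling cluster exceeded other microglia-like nuclei by at most 0.155% of another class's own marker level, in endothelial-like markers. A candidate explanation is division of microglia after the impact, but a difference between the animals of the 2 libraries was not tested and stays open.

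Glucocorticoid-responsive genes were lower in oligodendrocyte-like nuclei of the mTBI library. A few nuclei holding most UMIs are argued against, since the median without them was -1.03, outside the range of random lists of -0.18 to 0.20. The larger oligodendrocyte cluster held 733 of 802 mTBI and 983 of 1057 Sham nuclei, so the mix of the clusters was similar in both libraries. The median within that cluster alone was -1.02, but this value rests on nearly the same nuclei as the class. A different mix of nuclei within that cluster was not tested. Tissue taken at another time of day cannot be told apart from the groups, because the median of clock genes lay outside the middle 95% of random lists in 1 of the 4 classes examined and members such as Dbp (0.82) and Cry1 (-1.19) in oligodendrocyte-like nuclei went both ways. A lower hormone signal 48 hours after the impact may also account for it, and this was not tested.

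Gfap, Tuba1b, Mt1 and the oxidative phosphorylation and ribosomal protein genes were higher in nearly every class of the mTBI library. More free RNA of these transcripts in the mTBI droplets is a candidate explanation. Their excess per nucleus in deep classes was at most 1.35 times that in shallow classes, and 1.28 times for Slc25a4 and 0.897 times for Lars2. The mean of the class median depths differed by 3.71 to 3.90 times. These ratios cannot decide for free RNA, because all deep classes were neuronal and all shallow classes non-neuronal, so depth and cell type cannot be told apart. A general increase of free RNA is neither shown nor excluded by other transcripts. The ratio of excess, deep over shallow classes, was 0.860 for Ttr and 0.401 for Apoe, but 3.30 for Vim, 2.32 for Malat1 and 5.93 for Slc17a7. The Gfap ratio left out astrocyte-like and ependymal-like nuclei, whereas the Vim, Apoe and Slc17a7 ratios include classes with much of the transcript. Vim was at 1.10 and 1.30 UMIs per nucleus in endothelial-like nuclei of the mTBI and Sham libraries. Slc17a7 was at 3.87 and 3.63 in CA3-like neurons. In oligodendrocyte-like nuclei Ttr was at 2.04 and 1.77 and Slc17a7 at 0.608 and 0.530. Gene length as the whole cause is argued against for 15 of 24 pairs of list and class. Their median stayed above the middle 95% of random lists matched on length and expression. These random lists were themselves shifted upward, with a range of 0.04 to 0.37 against the oxidative phosphorylation median of 0.39 in granule-like neurons. Part of the excess was therefore shared by other genes of like length and expression, and these 2 were not told apart. For the other 9 of the 24 pairs length cannot be told apart from the difference between libraries, because the median lay within that middle 95%. Among them ribosomal protein genes stood only in endothelial-like nuclei. The rest were oxidative phosphorylation genes, in GABAergic-like, CA3-like, precursor-like, ependymal-like, fibroblast-like, immature granule-like, choroid plexus-like and endothelial-like nuclei. A difference within the cells themselves was not tested apart from free RNA.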

How the results depend on the processing

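The alternatives without the nucleus holding most UMIs, with the largest cluster of a class alone and without the cycling cluster were chosen only after the result was seen. No paired analysis was possible because each group has 1 library, and leaving out a replicate is impossible for the same reason, so no result comes from a test. Over the alternatives, 3758 values of gene log2 ratios stayed within the counting interval of their main value, 265 moved and 22 reversed. For list medians these counts were 497, 65 and 8, and for ratios of shares 119, 4 and 1. A change of direction was counted as reversed only where the main interval excluded a ratio of 1, or the main list median lay outside the middle 95% of random lists. Other changes of direction were counted as moved or as within the interval. Classes missing when a library was clustered alone, such as astrocyte-like, have no value there. Depth left out genes with under 50 UMIs in a class. For all values below the cause was not tested.

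With at least 200 UMIs, 59 instead of 160 pairs of gene and class were named, because fewer genes qualify. The glucocorticoid-responsive median in oligodendrocyte-like nuclei was -1.35 with at least 20 UMIs, with at least 200 UMIs and after thinning. With at least 200 UMIs ribosomal protein genes in granule-like neurons were at 0.68 and matrix genes in astrocyte-like nuclei at 0.0491.

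At a cluster resolution of 0.5, log2 ratios were -0.41 for Apoe in microglia-like, 0.34 for Il1rapl2 in immature granule-like and -0.47 for Prr5l in subicular-like nuclei. Medians there were 0.0290 for immediate early genes in subicular-like, 0.84 for mitochondrial transcripts in CA3-like and 0.0351 for glutamate receptor genes in endothelial-like nuclei. At a cluster resolution of 2, CT009510.2 in precursor-like nuclei was at 0.0140 and Il1rapl2 at 0.82. Medians were -0.81 for glucocorticoid-responsive and 0.55 for oxidative phosphorylation genes in oligodendrocyte-like, 0.0710 for immediate early genes in subicular-like and 1.01 for mitochondrial transcripts in CA3-like nuclei, and the oligodendrocyte-like share ratio was 0.898. At that resolution a shallow cluster of 1068 nuclei (439 mTBI and 629 Sham) with 9 of 9 oligodendrocyte markers went unnamed, so these oligodendrocyte-like values rest on the remaining 605 and 186 nuclei of 2 clusters.

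With each library clustered alone, Apoe in microglia-like nuclei was at -0.41, CT009510.2 at 3.14, Col6a1 in CA3-like neurons at 3.70, Hrh1 at -2.38, Nhs at -0.86 and Zbtb16 at 0.0707 in subicular-like neurons, and Pdzrn3 at -0.00375 in endothelial-like nuclei. In CA3-like neurons the immediate early median was 0.0167 and the mitochondrial 0.97. Share ratios were 2.32 for CA3-like, 1.16 for endothelial-like and 0.80 for subicular-like nuclei.

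With doublets kept, microglia-like nuclei had homeostatic genes at -0.13, Dlg2 at -0.0196 and Dlgap1 at -0.00567. As means over nuclei, homeostatic genes were at -0.0863, mitochondrial transcripts at 0.74 in CA3-like and -0.39 in granule-like neurons, oxidative phosphorylation genes at 0.46 in granule-like neurons, and Gria4 at 0.24 and glutamate receptor genes at 0.0680 in endothelial-like nuclei.

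Under a mitochondrial limit of 2%, Cemip in endothelial-like nuclei was at -0.33, and mitochondrial transcripts at 0.76 in CA3-like, -0.30 in choroid plexus-like and -0.27 in granule-like nuclei. With no limit they were at 0.98 in CA3-like and -1.10 in choroid plexus-like nuclei. With size factors, and in the largest cluster alone, they were at -0.46 in granule-like neurons. In the largest cluster alone Gpc5 in fibroblast-like nuclei was at -0.28 and Ndnf in GABAergic-like interneurons at 0.80. Without the nucleus holding most of its UMIs Il1rapl2 was at 0.0165.

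After thinning, endothelial-like nuclei had Cntnap5a at 0.0346, Gria4 and the median of glutamate receptor genes at 0.0573, and glucocorticoid-responsive genes at 0.0222. Cholesterol genes in astrocyte-like nuclei were at 0.51, homeostatic genes at -0.12 and Dlgap1 at -0.0154 in microglia-like nuclei, neuropeptides at 0.76 in GABAergic-like interneurons, and mitochondrial transcripts at 0.71 in CA3-like, -0.92 in choroid plexus-like and -0.38 in granule-like nuclei.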

Other observations

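The synaptic lists and their classes were picked, and the alternatives with part of a class left out were chosen, only after the result was seen.

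The barrier and lining classes had their own differences. In choroid plexus-like nuclei, from the tissue that makes cerebrospinal fluid, Ap1s2, a vesicle coat adaptor, had 190 mTBI and 65 Sham UMIs and was 2.71-fold higher in the mTBI library (2.03–3.65). Por, the electron donor of cytochrome P450 enzymes, was 2.38-fold higher (1.60–3.63). Lower in the mTBI library were Maob, which breaks down amines, 2.28-fold higher in the Sham library (1.67–3.12), and Ghr, the growth hormone receptor, 1.91-fold (1.51–2.43). In ependymal-like nuclei, from the ciliated ventricle lining, Tcf7l2, a transcription factor of Wnt signalling, was 2.62-fold (1.77–3.95) and Cphx3 2.26-fold (1.61–3.22) higher in the Sham library, at log2 ratios of -1.39 and -1.18 that were -2.37 and -1.78 under a mitochondrial limit of 2%. In vascular leptomeningeal fibroblast-like nuclei Col8a1, a short-chain collagen, was 2.98-fold (1.91–4.72) and Ldb2 1.90-fold (1.56–2.32) higher in the Sham library, and the log2 ratio of Col8a1 was -1.57, or -0.97 after thinning. In oligodendrocyte precursor-like nuclei Nkain3 was 1.57-fold higher in the Sham library (1.37–1.80).

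Synaptic genes, which neurons express most, were higher in microglia-like nuclei of the mTBI library, by an amount that depended on the setting. There 16 of 18 glutamate receptor and postsynaptic genes were higher, with a median log2 ratio of 0.44 (0.29–0.52), and 15 of 18 synaptic adhesion genes, with a median of 0.43 (0.34–0.55). With doublets kept these medians were 0.05 and 0.10, and after thinning 0.07 and 0.29. In endothelial-like nuclei the medians were -0.38 (-0.63 to -0.21), with 4 of 17 higher, and -0.77 (-0.98 to -0.65), with 2 of 17 higher, but single nuclei carried much of this. Without the nucleus holding most UMIs of each gene the endothelial-like medians were -0.02 and -0.42, and after thinning 0.06 and -0.03. Tenm4, a synaptic adhesion gene, had 55.2% of its Sham UMIs in 1 endothelial-like nucleus.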
